A study of Homo sapiens with 299 samples.

How the data were processed

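Plasma from 4 groups was profiled, 1 library per sample. The diagnostic cohort had 121 PDAC and 82 control libraries, and the prediagnostic cohort 48 later cases and 48 controls. Per the labels' protocols, 15 µl of plasma was hybridised without RNA extraction to probes of the HTG EdgeSeq miRNA whole transcriptome assay, the probes were amplified by PCR and sequenced on a MiSeq. The deposited tables hold the authors' raw read counts per probe, in whole numbers, with 1 table per cohort. The tool that turned reads into counts is not given in the sources used here. Each table has 2102 probes, of which 2083 are for miRNAs and 19 are controls (5 negative, 1 positive and 13 housekeeping probes), and its row of totals matched the column sums in both cohorts, with a largest difference of 0. Control probes were kept out of library sizes and miRNA tests. The labels give no centre, batch, stage or time before diagnosis, so none of these could be a term in a model.

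Total miRNA counts had medians of 842294 (PDAC), 793786 (diagnostic controls), 454985 (prediagnostic cases) and 447190 (prediagnostic controls). No library was below 25% of its cohort's median depth, and no 2 libraries of a cohort were copies of each other. No columns were left out.

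Read counts were analysed in R 4.3.3 with edgeR 4.0.16. Scaling was by TMM, filterByExpr was applied with the groups (it removed no miRNA), and a robust quasi-likelihood model with the group as its only term was tested two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Both cohorts were tested alone. The difference of the case effect between cohorts was the interaction term of a model over 299 libraries with cohort and disease. Standard errors are those of the fitted log2 fold changes. Levels are CPM over all miRNA counts, without TMM factors, which is why ratios of the levels differ from the TMM fold changes. The median TMM factor was 0.570 in PDAC and 2.11 in diagnostic control libraries. Within each group its log2 rose with the log2 negative probe level (r = 0.907 in PDAC and 0.967 in control libraries). The TMM scale thus followed probe background.

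Depth, detected miRNAs (at least 10 counts), control probe levels and the haemolysis index (log2 of miR-451a over miR-23a-3p, pseudocount 0.5) were compared by two-sided permutation tests with 100000 resamples, 21 measures per cohort, with Benjamini-Hochberg adjustment. The smallest p they can give is 2e-05. These used python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

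The 17 lists of miRNAs were erythrocyte, platelet, leukocyte, liver, pancreas, muscle, brain, epithelial miR-200, PDAC tissue, PDAC circulating, let-7, miR-17-92, miR-34, miR-29 and miR-30, DLK1-DIO3, C19MC and endothelial. They were written from general knowledge, and 29 of their 164 miRNAs belong to more than 1 list. Plasma holds RNA from blood cells and many tissues, so no list is specific to 1 source. Each was tested with limma 3.58.1 camera with a preset correlation of 0.01 and with an estimated correlation, beside fry. These tests used log2 CPM with TMM factors, except under total counts.

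Classifiers were fitted with glmnet 4.1.10 on log2 CPM with TMM factors (prior count 2). They had 10 outer folds, with miRNA selection inside each fold. The TMM factors were computed over all libraries of a cohort, held-out ones included. The diagnostic model was applied to the prediagnostic cohort after standardising each miRNA within its cohort. Intervals of the AUC are from pROC 1.19.0.1. The lasso with held-out folds was refitted on 20 permuted label sets.

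The named miRNAs followed a rule set before the data were examined, as were the main tests, lists and a first set of alternatives. Per cohort, among miRNAs past the threshold at or above the median mean log2 CPM, the rule takes the 12 largest increases and the 12 largest decreases. With fewer than 5 such miRNAs it takes the 10 with the smallest p. It also takes up to 10 miRNAs past the threshold in the same direction in both cohorts, the first-listed and up to 3 most significant members of each list, the 5 largest interactions, miR-451a and miR-23a-3p, and up to 10 miRNAs of the lasso model by weight. The text names 65 of the miRNAs the rule takes, picked after their values were seen. miR-30c-5p, miR-331-3p and miR-4667-5p lie outside the rule and were chosen after their values were seen.

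Alternatives set in advance were DESeq2 size factors, upper-quartile scaling, total counts, no filter, a filter at 50 counts in 50% of libraries, DESeq2 1.42.0, limma with voom and sample weights, the Wilcoxon test, depth, the haemolysis index or up to 5 surrogate variables (sva 3.50.0) as covariates, removal of libraries with low depth or a haemolysis index over 7, and adjacent title numbers as a block in the prediagnostic cohort. After seeing the data, alternatives built on the control probes were added. They took the negative probe level, or the negative and positive probe levels, as covariates, scaled to the positive probe, kept libraries with negative probes below 30 CPM, or kept libraries in the positive probe range that both groups share. A further one tested only probes above background, meaning counts over 3 times the highest negative probe plus 10 in at least 75% of libraries (236 probes in the diagnostic and 124 in the prediagnostic cohort). Fits without the libraries highest in the called prediagnostic miRNAs, classifiers with the control probes removed or alone, and a classifier within the prediagnostic cohort were also added then. In the simulated data used to test edgeR at the sizes of the 2 cohorts, 100 of 2083 miRNAs changed at each fold. In the diagnostic layout 87% of 1.5-fold and 98% of 2-fold changes were recovered, with 11 false calls. The prediagnostic layout had 86%, 100% and 5 false calls. Simulated miRNAs varied independently of each other, which the real ones did not.

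Precursor genes were matched by name in GENCODE release 29 (GRCh38), so mature miRNAs with several precursors have several positions. Sequence differences between miRNAs of a family were not used here.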

Results

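MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured in 299 human plasma samples, with 1 library per sample. The diagnostic cohort held 121 libraries from people with pancreatic ductal adenocarcinoma (PDAC, the most common cancer of the pancreas) and 82 control libraries. The prediagnostic cohort held 48 libraries from people whose PDAC was diagnosed later and 48 matched controls. The study asked whether plasma miRNAs separate early PDAC from controls, and whether the difference is already present before diagnosis. Each library gave counts for 2083 miRNA probes and 19 control probes. Total miRNA counts per library ranged from 275413 to 2007589 in the PDAC group and from 371707 to 1365285 in the diagnostic controls. In the prediagnostic cohort they ranged from 276026 to 658770 in the later cases and from 222924 to 677032 in the controls. Levels below are miRNA counts scaled to a common total (CPM), as mean ± SD over libraries.

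Some abundant plasma miRNAs were higher and others lower in PDAC than in control plasma. All 8 measured members of the let-7 family, which are known for restraining growth-promoting transcripts, rose. let-7a-5p had 6490 ± 2768 CPM (n = 121) in PDAC plasma and 3202 ± 1530 CPM (n = 82) in control plasma. miR-221-3p, which is known to target cell-cycle inhibitors, rose from 2838 ± 2175 to 9104 ± 4785 CPM. miR-145-5p and miR-143-3p, which are made from 1 precursor cluster and are typical of smooth muscle and stroma, rose from 417 ± 260 to 1155 ± 610 CPM and from 400 ± 297 to 1041 ± 673 CPM. In edgeR with TMM scaling, 751 miRNAs were higher and 1067 lower in PDAC plasma at a Benjamini-Hochberg adjusted p under 0.05, of 2083 tested. The split depended on the scaling. Total miRNA counts alone gave 183 higher and 1784 lower, upper-quartile scaling 452 and 1434, and DESeq2 size factors 849 and 940. The median log2 fold change of all 2083 miRNAs was −0.24 with TMM, −0.08 with DESeq2 size factors, −0.85 with upper-quartile scaling and −1.67 with total counts, so each fold change is relative to that shift.

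The control probes of the assay differed between the same groups. The positive control probe had 2205 ± 1459 CPM in PDAC libraries and 25748 ± 20100 CPM in control libraries, a geometric mean ratio of 0.107 (two-sided permutation test, adjusted p = 3.2e-05 over 21 measures, from the smallest p the resamples can give). The 5 negative control probes averaged 20.3 ± 51.1 CPM in PDAC and 77.8 ± 73.5 CPM in control libraries, a geometric mean ratio of 0.156 (adjusted p = 3.2e-05). A library had 1296 ± 472 miRNAs with at least 10 counts in the PDAC group and 1919 ± 343 in controls (adjusted p = 3.2e-05). Depth differed less, with a mean log10 total of 5.93 ± 0.12 against 5.89 ± 0.12 (adjusted p = 0.025). In the prediagnostic cohort, none of these 21 measures passed the adjusted threshold. Its positive probe had 29454 ± 10768.5 CPM in cases and 31661 ± 10772 CPM in controls, and its negative probes 125.5 ± 115.4 and 113.2 ± 83.7 CPM.

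**Figure D1:**
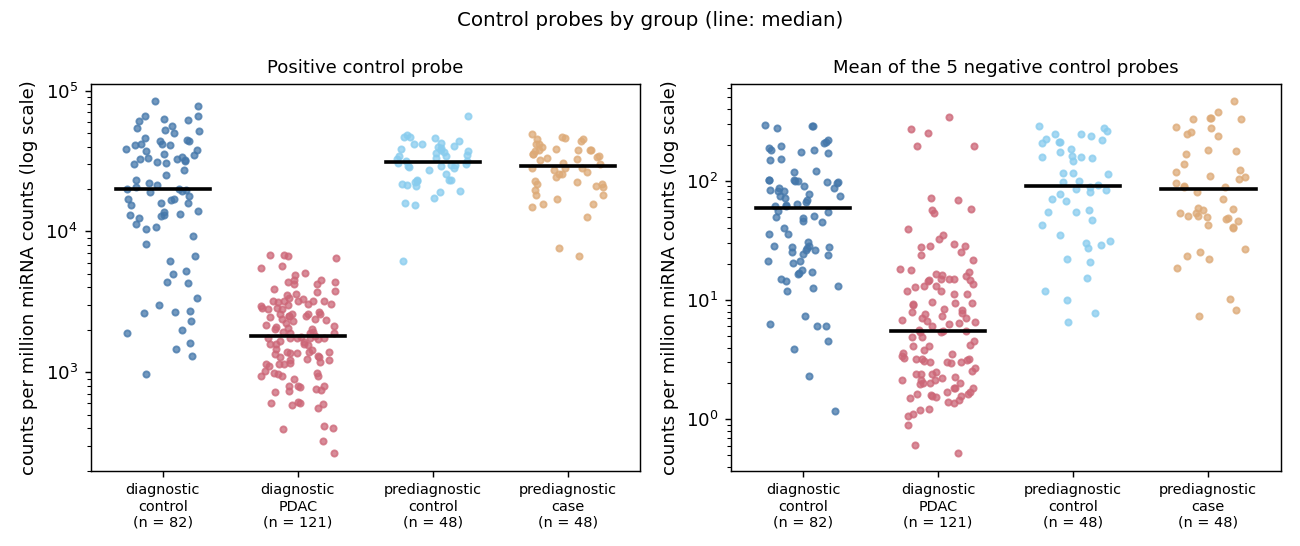
Positive control probe (left) and mean of the 5 negative control probes (right) in CPM on a log scale, with 1 point per library and a line at each group median. In the diagnostic cohort the PDAC libraries have a median positive probe level of 1816 CPM against 19936 CPM in controls, while the prediagnostic groups have medians of 29214 and 30995 CPM.

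Among the more abundant miRNAs, the 12 largest TMM increases in PDAC plasma ran from a log2 fold change of 2.88 to 4.58. miR-3687 came first (log2 fold change 4.58, SE 0.37, adjusted p = 4.62e-25), followed by miR-6752-5p, miR-4525 and miR-4417 at 4.03, 3.70 and 3.55. Levels of these 4 varied widely between PDAC libraries, with miR-6752-5p at 16911 ± 37819 CPM. The median of miR-3687 was 127 CPM in PDAC and 133 CPM in control libraries, beside means of 754 ± 2208 and 170 ± 156 CPM. With the negative and positive probe levels as covariates, miR-4417 turned to −1.41 (adjusted p = 0.038), while miR-3687, miR-6752-5p and miR-4525 had −1.14, −1.22 and −0.81 and did not pass. The other 8 were miR-221-3p, miR-145-5p, miR-744-5p, miR-143-3p, miR-625-5p, miR-222-3p, miR-425-5p and miR-199a-5p, at 3.08, 3.03, 3.0, 2.99, 2.97, 2.88, 2.88 and 2.88. All 8 were also called higher with total counts, at 1.33 to 1.68. With both covariates, 6 of these 8 stayed called higher, among them miR-145-5p at 0.96 (SE 0.23, adjusted p = 0.0023). miR-425-5p and miR-199a-5p had 0.57 and 0.56 there and did not pass.

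The largest TMM decrease was that of miR-197-5p, from 4000 ± 8130 CPM in control to 233 ± 170 CPM in PDAC plasma (log2 fold change −2.60, SE 0.23, adjusted p = 1.41e-22). It had −4.10 with total counts, and −1.13 (adjusted p = 0.052) with both covariates. In libraries of the shared positive probe range it had 0.33 over all probes and −1.42 on probes above background. The next decreases, led by miR-1912 (−2.40), miR-1468-3p (−2.23), miR-155-3p (−2.18), miR-208b-3p (−2.16) and miR-200c-5p (−2.09), were of probes near background, with 16.4 to 21.5 CPM on average in PDAC plasma. With both covariates these 5 had −0.13, −0.22, −0.33, −0.24 and −0.21, and none passed. Of the 1067 lower calls, 1036 were on probes that exceeded background in at most 10% of libraries. Their median log2 fold change was −0.72, beside a mean of −0.81 for the negative control probes in the same scaling. Of the 751 higher calls, 91 were on such probes. On the other probes higher calls thus far outnumbered lower ones with TMM. A TMM count of higher members in a list of detected miRNAs therefore says little about that list in particular.

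**Figure D2:**
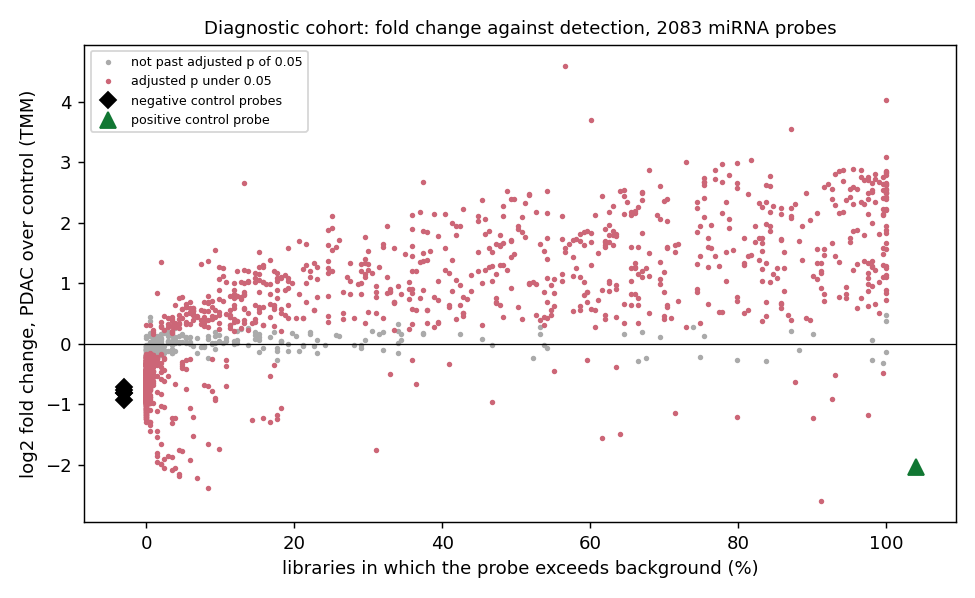
TMM log2 fold change of PDAC over control plasma (vertical axis) against the percentage of the 203 diagnostic libraries in which a probe exceeds background (horizontal axis), with 1 point per miRNA probe, coloured by whether it passed the adjusted threshold. Black diamonds (5 negative control probes, −0.94 to −0.72) and the green triangle (positive control probe, −2.05) are drawn beside the percentage axis, and only their heights are measured.

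Restricting the test to the 236 probes above background gave 44.5% higher and 37.7% lower, and 69 of the 224 TMM calls among them were called in the opposite direction. With a filter at 50 counts in 50% of libraries, 151 of 528 were. With both control probe levels as covariates, 45 miRNAs were higher and 148 lower, and 81 of the 1818 TMM calls remained in their direction while 71 were called in the opposite one. The settings with background and control probes were chosen after seeing the data.

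The let-7 family had 8 of 8 members called higher under each of the 4 scalings. Their median log2 fold change was 2.48 with TMM and 0.92 with total counts. let-7i-5p had 2.80 (SE 0.23, adjusted p = 2.04e-25) and let-7a-5p 2.54, let-7b-5p 2.55 and let-7d-5p 2.59. On probes above background alone, 8 of 8 were higher with a median of 0.63, and with both covariates 5 of 8 were higher with a median of 0.64. In the 98 PDAC and 18 control libraries whose positive probe level lay in the range both groups share (964 to 6833 CPM), tested on probes above background, 6 of 8 were higher, and let-7a-5p had 0.66 (SE 0.11, adjusted p = 1.65e-06). The control probes still differed in this range. Median negative probe levels were 6.57 CPM in PDAC and 23.9 CPM in control libraries, and median positive probe levels 2201 and 2699 CPM. With the negative probe level added as a covariate, 4 of 8 were higher. Members of this family differ by few bases, so probes can share signal and single members are uncertain. All 8 let-7 members passed when adjusted over the list alone. The set test of the list had an adjusted p of 4.22e-07 with camera's preset correlation and adjusted p = 0.159 with an estimated correlation (0.0022 with total counts).

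**Figure D3:**
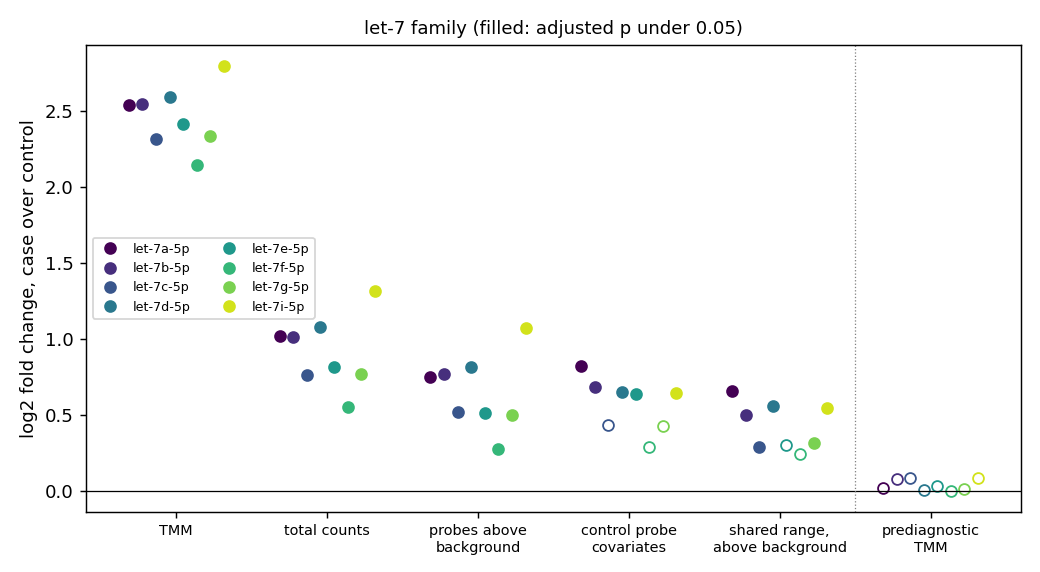
log2 fold changes of the 8 let-7 family members (colours) in the diagnostic cohort under 5 settings and, right of the dotted line, in the prediagnostic cohort with TMM. Filled points passed an adjusted p of 0.05. The median is 2.48 with TMM, 0.63 on probes above background, 0.41 on those probes in libraries of the shared positive probe range, and 0.03 in the prediagnostic cohort.

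The miR-17-92 family, whose clusters are known as growth-promoting, rose in 14 of 14 members with TMM and with total counts, with medians of 2.63 and 1.18. miR-17-5p went from 1657 ± 984 to 3930 ± 1838 CPM and miR-18a-5p from 455 ± 267 to 1117 ± 504 CPM. With both covariates 1 of the 14 was called. The miR-29 and miR-30 list rose in 8 of 8 members with TMM and 7 of 8 with total counts, including miR-29a-3p (2.43 with TMM) and miR-30e-5p (2.75), and 1 of 8 was called with both covariates. Adjusted over the list alone the TMM and total-count numbers were the same, and with both covariates 10 of 14 and 5 of 8 were called higher. With TMM their set tests had adjusted p values of 1.28e-11 and 1.7e-06 with the preset correlation, and adjusted p = 0.159 for both with an estimated correlation. With total counts these were adjusted p = 0.0016 and 0.010 with an estimated correlation.

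Lists of blood-cell miRNAs rose with TMM in the same libraries, as did most called probes that were not at background. Camera compares a list with the other miRNAs tested, and 1306 of the 2083 probes exceeded background in at most 10% of libraries. The platelet list had 10 of 10 members higher, including miR-126-3p (2.23, which is also an endothelial miRNA) and miR-191-5p (2.85). The erythrocyte list had 9 of 10 higher, including miR-451a (2.21), miR-486-5p (2.51), miR-16-5p (2.56) and miR-92a-3p (2.64). The leukocyte list had 8 of 8 higher, including miR-223-3p (2.66), a myeloid miRNA, and miR-181a-5p (2.80). With total counts the platelet list had 9 higher and 1 lower, the erythrocyte list 6 and 4, and the leukocyte list 4 and 3. miR-155-5p, a leukocyte miRNA, had 1.62 with TMM and −0.28 with total counts (adjusted p = 0.015). With both covariates each of these 3 lists had 1 member called higher and none lower. Counts adjusted over the list alone were the same with TMM, and with both covariates 4 platelet, 3 erythrocyte and 2 leukocyte members were higher and 1 erythrocyte member lower. miR-451a had −0.01 on probes above background in the shared positive probe range. The set tests gave adjusted p values of 2.73e-07, 2.18e-05 and 1.13e-05 for the platelet, erythrocyte and leukocyte lists, and adjusted p = 0.159 for all 3 with an estimated correlation. With total counts the 3 had adjusted p = 0.0044, 0.0016 and 0.018 with an estimated correlation.

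Among lists of solid tissues, the liver list had 4 of 4 members higher with TMM and 2 higher and 2 lower with total counts. Its abundant member miR-122-5p, the main hepatocyte miRNA, had 1377 ± 1875 CPM in PDAC and 702 ± 1099 CPM in control plasma (1.95, SE 0.29), but −0.34 (adjusted p = 0.598) on probes above background in the shared positive probe range. miR-192-5p had 1.82. The pancreas list had 3 of 7 higher and 3 lower. miR-216a-5p, an acinar miRNA, had 0.57 with TMM and −1.03 with total counts (adjusted p = 5.4e-09), and the islet miRNA miR-375 had 0.44 and −1.10 (adjusted p = 1.71e-08). miR-216b-5p and miR-802 had −0.91 and −0.92 with TMM. miR-148a-3p, which is abundant in pancreas and liver, rose from 454 ± 198 to 669 ± 347 CPM (2.24 with TMM, 0.56 with total counts). The muscle list had 3 of 6 higher and 3 lower, and miR-1 turned from 1.08 with TMM to −0.90 with total counts, while miR-133b went from 1.85 to −0.07. The brain list had 2 of 6 higher and 3 lower, with miR-128-3p at 2.68, miR-124-3p at 0.56 (−1.08 with total counts) and miR-137 at −0.87. The epithelial miR-200 list had 2 of 6 higher and 3 lower, with miR-200c-3p at 1.26 (−0.47 with total counts) and miR-200a-3p at −0.54. With total counts the pancreas list had 1 higher and 6 lower, the muscle list 0 and 4, the brain list 1 and 5, and the miR-200 list 0 and 6. The liver set test had adjusted p = 0.024, and adjusted p = 0.216 with an estimated correlation. With TMM the other 4 lists of this paragraph did not pass camera, and of these the muscle list passed fry towards lower (adjusted p = 0.033), while with total counts all 4 passed fry towards lower. With TMM the 12 lists called by camera in the diagnostic cohort also passed fry in the same direction.

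Among lists tied to PDAC or to gene clusters, the tissue list of PDAC-associated miRNAs had 13 of 16 members higher and 1 lower with TMM, and 8 and 8 with total counts. Its best known member miR-21-5p rose from 4719 ± 2609 to 6947 ± 3981 CPM (2.14 with TMM, 0.56 with total counts) and had −0.01 with both covariates and −0.06 on probes above background in the shared positive probe range. The list of circulating miRNAs linked to PDAC had 21 of 22 higher and 1 lower, and 17 and 5 with total counts, including miR-181b-5p (2.19). The endothelial list had 9 of 11 higher and 1 lower, and 4 and 6 with total counts. The list of the imprinted DLK1-DIO3 cluster had 28 of 33 higher and 3 lower with TMM, including miR-127-3p (2.24), but 9 and 14 with total counts and none with both covariates. The placental C19MC list had 0 of 20 higher and 19 lower, including miR-512-3p (−0.87) and miR-519a-3p (−0.82), at a median share of 0 libraries above background. The miR-34 list had 1 of 7 higher and 6 lower. Its higher member miR-34a-5p, a p53 target, had 2.03 with TMM and 0.24 (adjusted p = 0.124) with total counts, and 1.19 (SE 0.22, adjusted p = 3e-05) with both covariates. miR-34b-3p fell from 675 ± 570 to 109.1 ± 80.1 CPM and miR-34c-5p from 187 ± 149 to 36.2 ± 47.3 CPM, and both stayed called lower with both covariates at −0.65. In libraries of the shared positive probe range they had 0.29 and 0.012 and were not called, and with scaling to the positive probe 0.22 and 0.56. The tissue, circulating, endothelial, DLK1-DIO3 and C19MC set tests passed with the preset correlation, and had adjusted p = 0.159, 0.159, 0.173, 0.272 and 0.332 with an estimated correlation. With total counts the tissue and circulating lists had adjusted p = 0.026 and 0.0016 with an estimated correlation. With TMM the miR-34 list did not pass camera (adjusted p = 0.532), but passed fry towards lower (adjusted p = 5.54e-08), which does not compare a list with other miRNAs.

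Precursor genes of the miRNAs named most often were located by name in the GENCODE release 29 annotation of the GRCh38 genome. MIR143 lies on chromosome 5 from 149428918 to 149429023 in an exon of the long noncoding RNA CARMN, and MIR145 from 149430646 to 149430733 in an intron of it. MIR221 and MIR222 lie on chromosome X from 45746157 to 45746266 and from 45747015 to 45747124, in introns of MIR222HG. let-7a-5p can come from 3 precursors. These are MIRLET7A1 on chromosome 9 (94175957 to 94176036, intronic), MIRLET7A2 on chromosome 11 (122146522 to 122146593, in an intron of MIR100HG) and MIRLET7A3 on chromosome 22 (46112749 to 46112822, in an exon of MIRLET7BHG). MIR34A lies on chromosome 1 from 9151668 to 9151777 in an exon of MIR34AHG, and MIR451A on chromosome 17 from 28861369 to 28861440 in an exon of a long noncoding RNA.

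Before diagnosis, no list had a member past the threshold over all miRNAs, and only 2 of 2083 miRNAs were called. miR-6800-5p was higher in later cases (log2 fold change 2.31, SE 0.40, adjusted p = 1.92e-04) and miR-4271 lower (−2.37, SE 0.45, adjusted p = 7.08e-04). MIR6800 lies in an exon of MED25 on chromosome 19 (49832018 to 49832099) and MIR4271 outside any gene on its strand on chromosome 3 (49274120 to 49274186). Each call rested on 1 library. A case library had 30990 CPM of miR-6800-5p, beside 792 CPM in the next highest library and a median of 418 CPM. A control library had 194806 CPM of miR-4271, beside 7889 CPM in the next highest and a median of 3785 CPM. Without these 2 libraries edgeR called 0 miRNAs, and 34 had an unadjusted p under 0.05. DESeq2, limma with voom weights and the Wilcoxon test on all 96 libraries also called 0, with 38, 206 and 28 at an unadjusted p under 0.05. The third smallest adjusted p was that of miR-649 (log2 fold change 0.48, adjusted p = 0.512).

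miR-148a-3p had 194.5 ± 117.5 CPM in later cases and 155.2 ± 82.97 CPM in controls (log2 fold change 0.37, SE 0.12, unadjusted p = 0.002) and did not pass over all miRNAs. It was the 1 member of the pancreas list called higher when adjusted over the list alone. The let-7 members had a median log2 fold change of 0.03 and the 10 erythrocyte miRNAs 0.07. Set tests with the preset correlation called the liver (adjusted p = 0.0086), miR-200 (0.04), PDAC tissue (0.0012) and endothelial (5.88e-04) lists higher. With an estimated correlation these had adjusted p = 0.283, 0.283, 0.315 and 0.283. With both control probe covariates, a fit chosen after seeing the data, the PDAC tissue and endothelial lists passed camera with an estimated correlation (adjusted p = 0.038 each). These lists share members such as miR-145-5p and miR-143-3p, so they are not separate results. Their median members exceeded background in a share of 0.17 and 0.10 of libraries. On probes above background 3 PDAC tissue members were left (camera with an estimated correlation, adjusted p = 0.230), and the endothelial list was not tested. In the fit with both covariates 10 lists passed with the preset correlation, and fry passed for the PDAC tissue and endothelial lists (adjusted p = 0.018 each). With TMM none of the other 13 lists passed camera, and the smallest adjusted p of fry over the 17 lists was 0.419. In simulated data with the counts, depth and spread of this cohort, 86% of miRNAs changed by 1.5-fold and 100% of those changed by 2-fold were recovered. The simulated miRNAs varied independently of each other, with 5 false calls, while 1 draw of the real labels called 800 miRNAs. The simulation therefore does not show how many changes could be found in the real libraries.

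**Figure D4:**
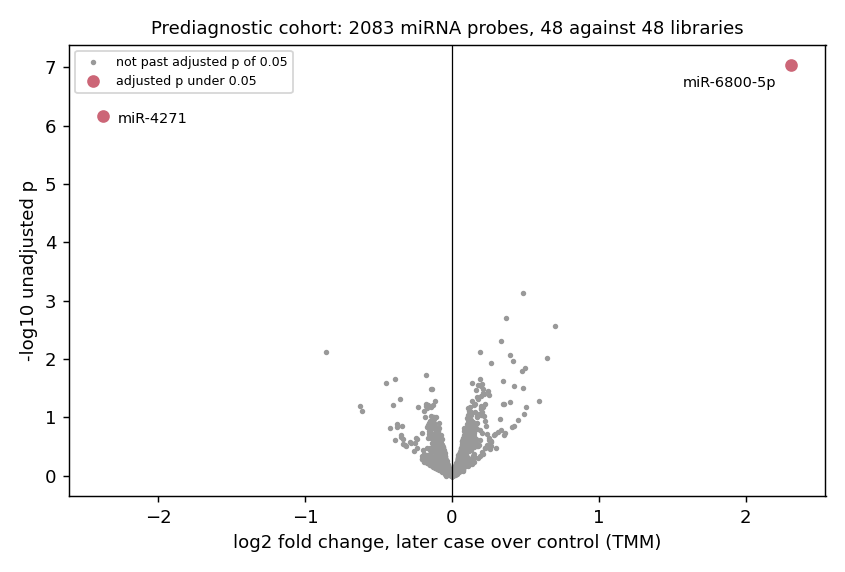
Unadjusted p on a −log10 scale against log2 fold change of later cases over controls for the 2083 miRNA probes of the prediagnostic cohort (48 against 48 libraries). miR-6800-5p and miR-4271, which each owe their call to 1 library, stand apart from all other probes.

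The directions found after diagnosis were compared with those before it. Of the 1818 miRNAs called in the diagnostic cohort, 921 (50.7%) had the same sign in the prediagnostic fit. The log2 fold changes of the 2 cohorts had a Pearson r of 0.048 and a Spearman rho of 0.040 across miRNAs, which are not independent replicates. With limma and voom weights in both cohorts 76.5% had the same sign and r was 0.582, and with total counts 21.9% and −0.09. miR-6800-5p was the 1 miRNA called in both in the same direction, beside 0.361 expected for independent lists of higher calls. It had 0.61 in the diagnostic cohort with TMM and −1.01 with total counts. miR-4271 was called in opposite directions.

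The case effect was tested for a difference between the cohorts in a single model over 299 libraries. It differed for 1644 miRNAs, being higher in the diagnostic cohort for 722 and lower for 922. let-7a-5p had a difference of 2.57 (SE 0.33, adjusted p = 1.86e-12), miR-145-5p 2.58, miR-221-3p 2.87 and miR-21-5p 2.02. With total counts the split was 131 and 1743, and with both control probe covariates 53 and 77.

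Red-cell RNA was followed by the haemolysis index, the log2 ratio of miR-451a to miR-23a-3p. It was 2.77 ± 1.69 in PDAC and 3.04 ± 1.24 in control libraries (two-sided permutation test, p = 0.22, adjusted p = 0.26). With miR-486-5p in place of miR-451a it was −0.71 ± 1.19 and −1.09 ± 0.97, higher in PDAC (p = 0.017, adjusted p = 0.024). The reference miR-23a-3p was itself higher in PDAC on probes above background (edgeR, log2 fold change 0.83, adjusted p = 5.92e-12), beside 0.67 for miR-451a. A difference of the index is therefore not specific to red-cell RNA. In the prediagnostic cohort the index was 4.66 ± 0.65 in cases and 4.95 ± 0.70 in controls (p = 0.039, adjusted p = 0.28).

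A lasso classifier used log2 CPM with TMM factors, which followed probe background. It separated PDAC from control libraries with a 10-fold held-out area under the ROC curve (AUC) of 0.957 (95% interval 0.925 to 0.990). The highest AUC among 20 refits on permuted labels was 0.571, which gives p = 0.048, the smallest p they allow. Of its 43 miRNAs, the largest weights were those of miR-6727-5p (against PDAC) and miR-1301-3p (towards PDAC). miR-6727-5p had 4273 ± 3447 CPM in PDAC and 16480 ± 8800 CPM in control plasma. The positive control probe alone, which measures no miRNA, gave an AUC of 0.931 (0.892 to 0.970), and the negative probes alone 0.863. With the control probe levels removed by regression the lasso had an AUC of 0.450 in the diagnostic cohort. Because these probes separate the groups, the regression also removes group differences of any other source along them. This AUC therefore does not show what the lasso rests on. Applied to the prediagnostic cohort, the diagnostic model had an AUC of 0.548 (0.432 to 0.665, two-sided permutation test, p = 0.42). A lasso trained and tested within the prediagnostic cohort had 0.460 (0.344 to 0.576).

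**Figure D5:**
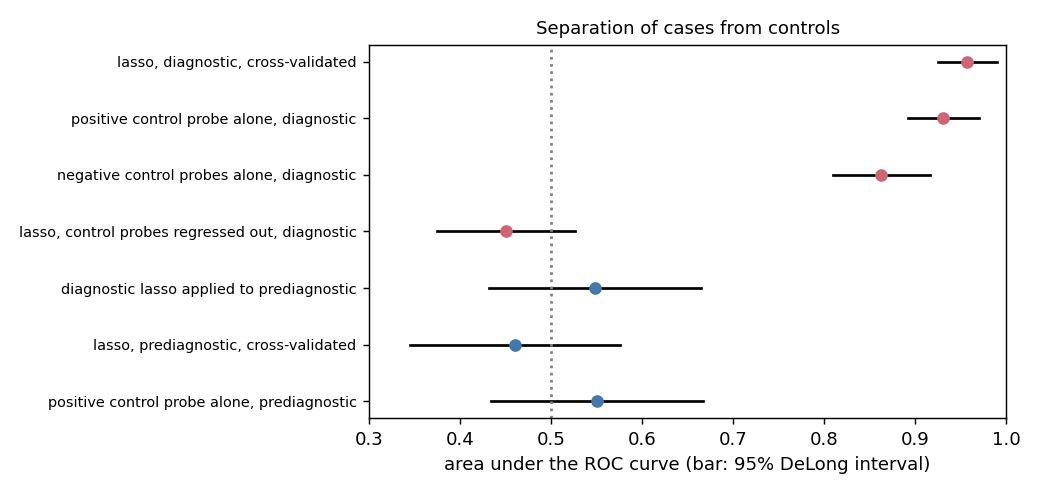
Area under the ROC curve (horizontal axis) with 95% DeLong intervals for miRNA classifiers and for control probes alone, in the diagnostic (red) and prediagnostic (blue) cohorts. The dotted line marks 0.5. The positive control probe alone reaches 0.931 in the diagnostic cohort, beside 0.957 for the lasso.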

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

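The tests of probe background, of the shared positive probe range, of the control probe covariates on let-7 and of single libraries were chosen after the results were seen, while the tests of other label draws, of signal following the positive probe and of platelet content were written before theirs.

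The case effect differed between the cohorts for 1644 miRNAs, by the interaction test of the cohort with disease. The 5 largest differences, diagnostic minus prediagnostic, were those of miR-3687 (4.43), miR-4271 (4.4), miR-6752-5p (4.19), miR-4525 (3.69) and miR-7150 (3.52). That of miR-4271 rests in part on 1 prediagnostic control library, since its prediagnostic log2 fold change of −2.37 was 0.20 without that library. Among 40 draws of the labels within each cohort, only the real one (value 1) called as many, and the highest other draw called 41, so a random grouping of libraries is excluded as the cause. The diagnostic tables carry the control probe difference between groups and the prediagnostic tables do not, and with both control probe covariates 130 miRNAs differed. The interaction therefore does not separate a change in the course of the disease from a difference in how the diagnostic groups were collected or run.

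Housekeeping probes, which take no part in the miRNA tests, also differed in the diagnostic cohort. As a share of miRNA counts, the B2M probe was 3.67-fold higher in PDAC than in control libraries, the RNY3 probe 1.69-fold and the YWHAZ probe 1.42-fold. Their TMM log2 fold changes were 3.19, 2.33 and 2.44, so their direction was the same in both scalings. Other housekeeping probes, such as that of PPIA (0.476-fold), went the other way as shares of miRNA counts.

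For the first pattern weighed, the 1818 calls in the diagnostic cohort, of 100 draws of the labels, 1 (the real one) gave as many, and the highest other draw gave 547, which excludes a random grouping but shows strong structure among the libraries. For the 1036 lower calls on probes at background, a candidate explanation is a background that differs between the groups. With the negative probe level as a covariate, 17.8% stayed called lower. The negative probes alone separate the groups (AUC 0.863), so this covariate also removes group differences of any other source along them. The loss of calls therefore does not show their cause. For the 194 calls on probes above background, the fold change within the shared positive probe range was a median of 0.363 of that over all libraries (quartiles 0.137 to 0.582), so the amount of RNA captured and PDAC cannot be told apart, because the positive probe follows the groups. For the lower calls above background, signal that follows the positive probe and PDAC cannot be told apart. In the prediagnostic cohort their median partial correlation with the probe was 0.25 (49 of 62 above 0) and that of the higher calls 0.386 (19 of 27 above 0), and the difference of −0.136 (bootstrap SD 0.145, permutation p = 0.37) met the bound of under 0.1 set beforehand as evidence against, but the test covered only 69.7% of the lower and 25.7% of the higher calls, so it does not exclude this, a limit applied after the value was seen.

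The second pattern was the rise of the let-7 family. With both control probe covariates 5 of 8 members stayed called higher, a number known when the bound of 5 was set, and on probes above background in the shared positive probe range 6 did, but 4 with the negative probe level added. The median let-7 log2 fold change was 2.48 with TMM and 0.64 with both covariates (members 0.29 to 0.82). In the shared range it was 0.41, and 0.40 with the negative probe level added (members 0.19 to 0.53), so calls were lost with little change in fold. All 8 stayed above 0 in these fits. The members follow each other closely (estimated correlation 0.875 with both covariates), so their shared sign is not 8 separate results. Whether the control probe difference made all or part of the rise stays open. The positive probe follows the groups, and the control probes still differed in the shared range. A platelet score from 10 other miRNAs was 11.9 ± 0.455 in PDAC and 11.6 ± 0.356 in control libraries of the shared range, and the median let-7 log2 fold change with this score over that without it was 0.773. That reaches the bound of 0.75 set against platelets, but by less than the spread of the member ratios (SD 0.285, median 0.714), so platelet content and PDAC cannot be told apart for let-7.

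The third pattern was the pair of prediagnostic calls. Without the 2 libraries highest in miR-6800-5p and miR-4271, 0 calls were left (edgeR; 34 at an unadjusted p under 0.05; DESeq2, voom and the Wilcoxon test on all libraries 0), which is consistent with 1 library each as their source. All 100 of the 100 draws of the labels called at least 2 miRNAs, and the highest other draw called 800. The 2 outlying libraries fall in some group under any labels, so this count is a weak test of these calls. Chance is not excluded, and the libraries have a structure unrelated to the labels. What raised 1 probe in each of these libraries was not tested, and a biological source in that plasma stays open.

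Other draws also bear on the lists and on the comparison of cohorts. For the 12 lists called in the diagnostic cohort, 14 of 100 draws gave as many (highest other 14), and for the 4 in the prediagnostic cohort 46 of 100 did (highest other 13). The Pearson r of 0.048 between the cohorts' fold changes was reached in size by 86 of 100 draws (highest other 0.590). Chance is excluded for none of these 3.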

How the results depend on the processing

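The fits with control probe covariates, on probes above background, scaled to the positive probe, of low background or of the shared positive probe range, and without single libraries were chosen after the results were seen.

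In the diagnostic cohort, 751 miRNAs (36.1% of those tested) were higher and 1067 (51.2%) lower. The counts were within 1.5 times of these with DESeq2 size factors, DESeq2, voom, the Wilcoxon test, the depth and haemolysis covariates, surrogate variables and without the library over a haemolysis index of 7. Upper-quartile scaling gave 452 higher (21.7%) and 1434 lower. The other settings, as percent of tested miRNAs higher and lower, gave 8.79% and 85.6% (total counts), 44.3% and 37.1% of 569 (stricter filter), 44.5% and 37.7% of 236 (probes above background), 16.03% and 17.7% (negative probe covariate), 2.16% and 7.11% (both covariates), and 6.36% and 26.7% (both on probes above background). Scaling to the positive probe gave 99.2% and 0 (edgeR, where the unadjusted p counts do not separate directions). The level of this probe relative to miRNA counts differs between the groups, which sets this direction. Whether the probe or the amount of miRNA made that ratio differ was not tested. Libraries of low background gave 19.6% higher and 996 miRNAs lower, and libraries of the shared positive probe range 21.8% and 13.8%, or 13.6% and 14.8% on probes above background and 5.08% and 6.78% with the negative probe covariate too. The filters test fewer miRNAs, which lowers the counts, and for the rest the cause was not tested.

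Of the miRNAs of the naming rule called in this cohort, 20 had the opposite sign with total counts (17 of them called), 19 with both covariates (2 called) and 34 with scaling to the positive probe (25 called). With both covariates 70 more did not pass, and 22 passed in their direction. Over the rule's miRNAs named in the text, 78 values of both cohorts changed sign, as given here and in the next paragraph. The miRNAs named from outside the rule were not followed in this count. The TMM factors followed the negative probe level within each group (r = 0.907 in PDAC and 0.967 in control libraries), so the TMM scale itself follows probe background. What else turned these signs was not tested. Upper-quartile scaling gave −0.032 for miR-6800-5p, −0.082 for miR-216a-5p, −0.077 for miR-649, −0.13 for miR-124-3p and −0.17 for miR-375. Total counts gave −1.01 for miR-6800-5p, −0.28 for miR-155-5p, −1.03 for miR-216a-5p, −0.90 for miR-1, −1.08 for miR-124-3p, −0.47 for miR-200c-3p, −1.14 for miR-649, −1.10 for miR-375 and −0.073 for miR-133b. The stricter filter gave −0.71 for miR-6800-5p, and voom and surrogate variables −0.071 and −0.024 for miR-649. The negative probe covariate gave −0.23 for miR-6800-5p, 0.11 for miR-802, 0.047 for miR-137 and −0.053 for miR-375. Both covariates gave −1.14 for miR-3687, −1.22 for miR-6752-5p, −0.81 for miR-4525, −1.41 for miR-4417, −0.17 for miR-6800-5p, −0.21 for miR-1, −0.014 for miR-21-5p, −0.069 for miR-127-3p, −1.28 for miR-7150, −0.97 for miR-649, 0.070 for miR-802, 0.056 for miR-519a-3p and −0.057 for miR-375. On probes above background with both covariates, miR-6752-5p, miR-4417, miR-21-5p and miR-7150 had −1.64, −1.81, −0.26 and −1.66. Scaling to the positive probe gave 0.19 for miR-197-5p, 0.51 for miR-1912, 0.31 for miR-1468-3p, 1.01 for miR-216b-5p, 1.14 for miR-200a-3p, 0.56 for miR-34c-5p, 0.22 for miR-34b-3p, 1.06 for miR-512-3p, 0.036 for miR-561-3p, 0.97 for miR-802, 0.98 for miR-519a-3p, 1.11 for miR-137, 0.56 for miR-155-3p, 0.54 for miR-208b-3p and 0.57 for miR-200c-5p. The shared positive probe range gave 0.33 for miR-197-5p, 0.012 for miR-34c-5p, 0.29 for miR-34b-3p, 0.34 for miR-561-3p and −0.11 for miR-375. On its probes above background miR-451a, miR-122-5p, miR-21-5p and miR-7150 had −0.013, −0.34, −0.060 and −0.055, and with the negative probe covariate too −0.25, −0.32, −0.13 and −0.052.

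Both prediagnostic calls were kept with DESeq2 size factors, upper-quartile scaling, the stricter filter and scaling to the positive probe, and 1 or both were lost in the other settings. The DESeq2 test, voom, the Wilcoxon test, surrogate variables, the block of adjacent numbers, each control probe covariate fit, libraries of low background, probes above background within the shared range (without and with the negative probe covariate) and the fit without both libraries gave 0 higher and 0 lower, with 38, 206, 28, 145 and 24 at an unadjusted p under 0.05 in the first 5. The depth covariate and probes above background gave 0 higher and 1 lower, and total counts, the haemolysis covariate and the shared range 1 higher and 0 lower (edgeR; 47, 16, 15, 72 and 45 at an unadjusted p under 0.05). Without the library highest in miR-6800-5p 0 were higher, and without that highest in miR-4271 0 were lower. miR-6800-5p had −0.079 with DESeq2, −0.0051 with the block, −0.064 without its library and −0.062 without both. miR-4271 had 0.20 with DESeq2, 0.16 with voom, 0.19 in the shared range, 0.14 and 0.14 on its probes above background without and with the negative covariate, 0.062 with the block, 0.20 without its library and 0.13 without both. Single libraries account for both calls.

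No paired analysis was possible because the labels do not pair the samples of the diagnostic cohort. In the prediagnostic cohort the 48 couples of adjacent numbers each held 1 case and 1 control, but their profiles had a median r of 0.276 (lowest −0.70, 28 over 0.1) and 6 cases were most like their own control, beside a median r of 0.011 for other case and control combinations. The couples were thus more alike than other combinations, a hint of pairing from the data and not from the labels. Not every couple had an r over 0.1, so the block is an alternative only.

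The interaction gave 722 higher and 922 lower, 131 and 1743 with total counts, 53 and 77 with both covariates, and 773 and 1025 with voom. The Pearson r between the cohorts was 0.048 and went to 0.582 with voom, and the share of calls with the same sign went from 50.7% to 21.9% with total counts and 76.5% with voom. Other draws of the prediagnostic labels gave r from −0.58 to 0.59 with edgeR. The cause was not tested.

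The lists called numbered 12 in the diagnostic cohort, 0 with an estimated correlation, 6 of 9 tested on probes above background and 7 of 9 on those probes within the shared range. With total counts 12 were called, 8 of them with an estimated correlation too. Of these 12, camera called the liver, DLK1-DIO3 and endothelial lists higher relative to other miRNAs, but their medians were −0.11, −0.085 and −0.31. For these, fry pointed towards lower (adjusted p = 0.035, 0.0026 and 0.245). In the prediagnostic cohort they numbered 4, 8 with total counts, 10 with the haemolysis covariate, 0 with an estimated correlation, 10 with both covariates (2 of them with an estimated correlation too), 2 of 5 tested on probes above background and 2 of 5 on those probes within the shared range. The C19MC list kept a negative median with both covariates (−0.049), and its set test pointed to higher without passing (adjusted p = 0.352; 0.685 with an estimated correlation). The haemolysis difference in the diagnostic cohort, −0.27, was 0.38 with miR-486-5p. The AUC of 0.957 lay between 0.947 and 0.966 with elastic net, ridge, the haemolysis index removed or no scaling, and was 0.450 with the control probes removed, a regression that also removes group differences along those probes. The prediagnostic AUC values kept intervals that include 0.5. The detected miRNAs differed by −622 at 10 and −618 at 50 counts in the diagnostic cohort. The cause of these changes was not tested.

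No filter gave the same fit, since filterByExpr removed nothing. No library had under 25% of the median depth, and no prediagnostic library had a haemolysis index over 7, so those alternatives gave no value. Background was set by the negative probes, and 1306 diagnostic and 1588 prediagnostic probes exceeded it in at most 10% of libraries. Whether depth limits these probes was not tested.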

Other observations

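The tests of this part were all chosen after the results were seen.

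Across 7 settings of the diagnostic cohort (4 scalings, probes above background, both control probe covariates, and the shared positive probe range on probes above background), 11 of 236 miRNAs were called higher in each and 2 lower in each. The higher ones were let-7a-5p, let-7b-5p, let-7d-5p, let-7i-5p, miR-143-3p, miR-145-5p, miR-181a-5p, miR-221-3p, miR-222-3p, miR-30c-5p and miR-331-3p. The lower ones were miR-4667-5p, from 1002 ± 902 CPM in control to 234 ± 151 CPM in PDAC plasma, and miR-561-3p, from 1059 ± 1323 to 156 ± 99.99 CPM. miR-561-3p had 0.34 in the shared range over all probes, so its direction depends on which probes set the scale. The 15 other settings called all 11 higher miRNAs again, except probes above background in the shared range with the negative probe covariate. That fit kept 8, 4 of them let-7 members. These settings reuse the same libraries, so they are not independent tests. No filter was the same fit as the main one, and scaling to the positive probe called 99.2% of all miRNAs higher, so neither is a further test. The 2 lower miRNAs were not called with voom, the Wilcoxon test, scaling to the positive probe or the shared range over all probes, and of the 2 the fit that kept 8 called miR-561-3p alone.

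Among the 194 calls on probes above background, miRNAs with a miRBase number below 3000 or of the let-7 family had 83 higher and 35 lower, and those numbered 3000 or above had 22 higher and 54 lower (Fisher's exact test, two-sided, p = 1.58e-08; probes are not independent replicates).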
